A study of Mus musculus with 9 samples.

How the data were processed

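The deposited data are gene-level raw read counts from 9 libraries of stranded, polyA-enriched RNA of BG2 cells. These were 3 technical replicates of the wild-type bulk population and 3 each of 2 Sox10 knockout clones. The library names of the wild-type population hold NTC, read here as non-targeting control. Per the labels, the authors named fastp, Subread and DESeq2 and the mouse genome builds mm10 and GRCm38, without versions or settings. The unit of the deposited values is counts: whole numbers with no normalization, with 1 column per library; whether the authors pooled technical replicates in their own analysis is not given in the sources used here. The annotation and strand setting of the counting are not given in the sources used here. The labels call the replicates technical without saying at which step they parted, so p-values measure only the spread between these libraries, not between cultures or clones.

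The file held 24594 genes, of which 24570 had a symbol; the 24 others took at most 0.202% of a library's counts. Total counts were 66586056, 74460483 and 82605104 in the control, 65805296, 76608739 and 70895015 in clone 1, and 83282841, 75400269 and 77983011 in clone 2. The 10 most abundant genes took 4.49 to 5.80% of a library. A floor of 3 counts was used per quantity, over the 3 libraries of a group for folds and per library in the plot of single libraries. A fold against a group with 0 counts is a lower bound against that floor, a fold against 1 to 9 counts carries a 95% counting interval, and no fold is given where both groups lie at or under the floor. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

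Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 13928, scaled by TMM, and fitted in a quasi-likelihood model with 1 factor of 3 groups over all 9 libraries. Benjamini-Hochberg adjusted p under 0.05 counted as a difference. The contrasts were clone 1 minus control, clone 2 minus control, the mean of the clones minus control, and clone 2 minus clone 1; a gene called with the same sign in both clones was said to have risen or fallen in both. Values per group are means of TMM-scaled CPM (counts relative to library size) ± SD, n = 3. Log2 fold changes carry an approximate standard error, computed as their absolute value over the square root of the F statistic of the test. The common biological coefficient of variation was 0.0878. The agreement of the clones was set beside 20 simulated data sets of unchanged groups that shared the control libraries. After the results were seen, their calls were counted, and the agreement was computed again with a different control library for each clone.

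Before the data were examined, 30 gene lists with 545 members, the rule for named genes, the contrasts and most alternatives were fixed; alternatives added later are named in the closing section. The lists were tested with camera (limma 3.58.1) on voom values, preset correlation 0.01, 2-sided, adjusted over 90 tests (30 lists and 3 contrasts), and again with an estimated correlation and with fry. The lists covered luminal, basal, myoepithelial, milk, neural crest, Sox, mesenchymal, junction, ERBB, MAPK, cell cycle, p53, interferon, antigen presentation, Wnt, Notch, TGF-beta, YAP/TAZ, squamous, hypoxia, cholesterol, stress, heat shock, fibroblast, immune, endothelial and adipocyte genes. Named genes were Sox10; the 12 that rose and the 12 that fell most in both clones by the smaller change, with at least 5 CPM in a group and a symbol that is not a predicted model; the 8 highest and 8 lowest differences between clones; up to 4 members per list with the largest mean change and up to 2 called in opposite directions; and 20 mammary genes named in advance, of which Krt19 and Kit were too low to test. The ranks use fitted values, which for groups at 0 counts are no bounds, so they choose genes to name and do not order them by size. Some genes that met these rules are not reported here; counts of genes and list members include them. A difference of a named gene between clones was called by glmTreat at a log2 fold change of 1.

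The calls were tested on simulated counts of all 9 libraries, drawn from the control means with the dispersions of the real libraries. In these, 200 genes were changed in clone 1. The fit found 53 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 7 of 190 calls false. In the simulated clone 2, which was left unchanged, it called 0 genes. In a separate simulation only the list of basal genes was raised, 1.5-fold in clone 1. For clone 1 against control, camera ranked this list 1st and called 0 other lists. Genes were drawn independently, so this does not test camera on lists of correlated genes. The real data differ from this setting, since 76.5% of genes were called in clone 1 and 74.4% in clone 2. The 7 false calls of 190 are therefore no error rate for the real calls.

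Replicate numbers were checked as pairs. The deviations of same-numbered libraries from their group means correlated across genes at 0.177 to 0.663 for all pairs of groups, against -0.607 to 0.478 for other pairs. In 12 of 18 cases a library correlated best with its own number. The pairing was clear for replicate 1 (0.619 to 0.663). Among replicates 2 and 3 the other number was often closer, as for control 3 with clone 2 replicate 2 (0.478) and replicate 3 (0.177). Between replicate 1 and the others of its group the chi-square per degree of freedom was 25.6 to 49.7, and between replicates 2 and 3 it was 5.49 to 10.0. Replicate number was fitted as a block among the alternatives fixed in advance, and its values stand beside each named result whose call it changed. No sequencing date or batch is given in the sources used here.

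The alternatives were DESeq2 size factors, total counts without scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 with the Wald test, only the libraries of the groups compared, the replicate block, leaving out each library in turn, glmTreat, counts summed per population, and the settings of the list tests. Scaling moved the median log2 fold change of all genes to between -0.0247 and 0.0025. Gene positions, GC content and length came from the GRCm38 annotation. Splits of the libraries into other groups were counted for each contrast. Alignment, fusion, splicing and variants were not analysed here, since only gene counts were used.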

Results

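RNA sequencing measured the transcripts of BG2 cells, a cell line derived from a mammary tumour of an MMTV-NIC mouse, whose mammary epithelium expresses the oncogene Neu (rat Erbb2) together with Cre. The 9 libraries fell into 3 groups of 3 technical replicates each. These were the wild-type cells as a bulk population, named here the control, and 2 Sox10 knockout clones expanded from a CRISPR-edited population, clone 1 and clone 2. Each library held 65805296 to 83282841 counts, and 3 counts over a group corresponded to 0.0134 CPM (counts relative to library size) in the control, 0.0142 CPM in clone 1 and 0.0127 CPM in clone 2. The first principal component held 82.2% of the variance and parted the control from both clones, and the second held 15.8% and parted the clones. Replicate 1 stood apart from replicates 2 and 3 in every group.

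The first comparison asked whether the targeted gene was still transcribed. Sox10, a transcription factor of neural crest and mammary cells (Entrez ID 20665; chromosome 15, positions 79154913 to 79164490 on GRCm38, minus strand), was abundant in the control and nearly absent from both clones. Its counts were 16660, 21437 and 26038 in the control replicates, 0, 6 and 0 in clone 1, and 0, 2 and 2 in clone 2. The mean was 284 ± 40.9 CPM in the control, 0.0262 ± 0.0455 CPM in clone 1 and 0.0173 ± 0.0150 CPM in clone 2 (SD, n = 3 each). This was 10100-fold (95% counting interval 4640 to 27500) lower in clone 1 and 17000-fold (95% counting interval 6630 to 62300) lower in clone 2, with adjusted p of 7.46e-12 and 6.58e-12 in edgeR. The guides targeted exon 3 by the labels, without saying in which transcript. Exon 3 spans 79163289 to 79163794, with the first coding bases, in a transcript of 5 exons, and 79159135 to 79159403 in a transcript of 4 exons. Polr2f, the nearest gene on the 3' side, had log2 fold changes of 0.34 in clone 1 and 0.62 in clone 2. Gm10863, the nearest on the 5' side, had -1.58 and -1.14, and Pick1 beyond it had -1.20 and -0.74.

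**Figure D1:**
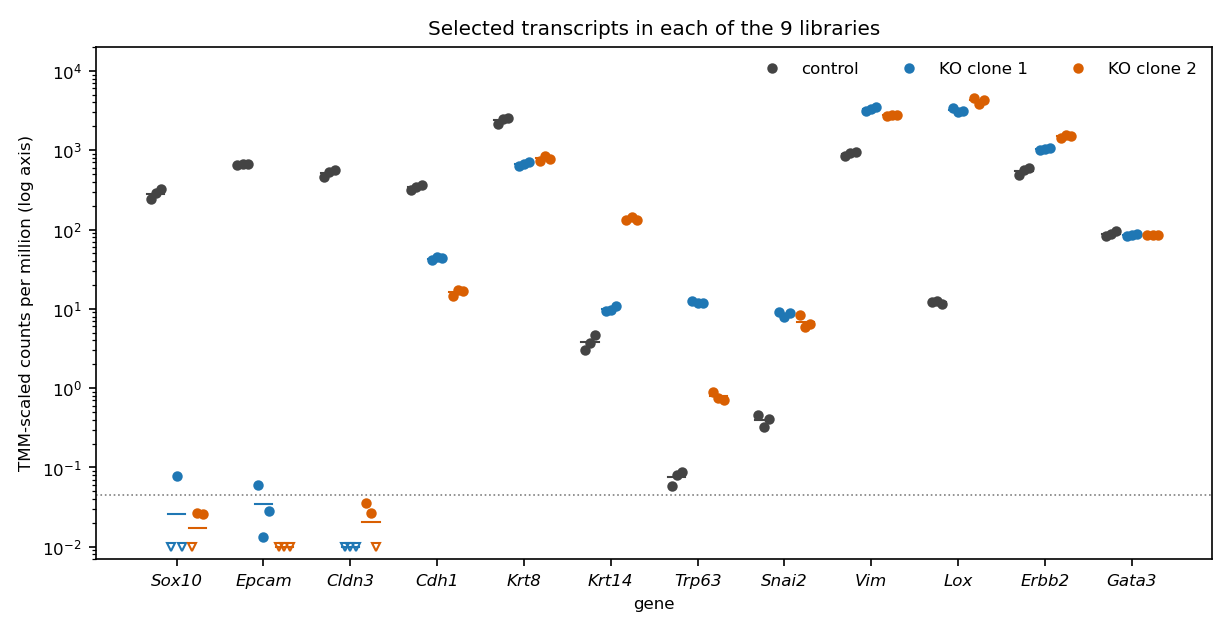
TMM-scaled CPM of 12 genes in each of the 9 libraries on a log axis, with a horizontal line at each group's mean; open triangles at the bottom mark libraries at 0 counts, and the dotted line is the highest per-library floor of 3 counts (0.0455 CPM). Sox10 lay between 240.7 and 321.8 CPM in the control libraries and at or below 0.0787 CPM in all 6 libraries of the clones, and Lox and Vim were higher in every library of the clones than in every control library.

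The next comparisons asked which transcripts differed between each clone and the control. In both clones most transcripts of epithelial junctions fell, several of them to the counting floor, and most of a list of mesenchymal transcripts rose. Epcam (Entrez ID 17075), an epithelial adhesion molecule on chromosome 17 at 87635979 to 87651127, fell from 659.5 CPM in the control to 0.0341 CPM in clone 1 and 0 counts in clone 2. Lox, a collagen cross-linking enzyme, rose from 12.1 CPM to 3199 CPM in clone 1 and 4234 CPM in clone 2. Of 13928 genes tested, 10653 (76.5%) differed in clone 1, 5282 higher and 5371 lower, of which 2267 and 2266 changed at least 2-fold. In clone 2, 10367 genes (74.4%) differed, 5194 higher and 5173 lower, of which 2099 and 2143 changed at least 2-fold. The same direction was called in both clones for 8090 genes, 3992 higher and 4098 lower, against 1969.8 and 1994.8 for independent calls, a value that leaves out the shared control. Simulated unchanged groups against that control gave at most 1 gene called in both in the same direction, and 148.6 on average at an unadjusted p under 0.05 in both (edgeR, 20 data sets). These groups were drawn with the spread between technical replicates only. They therefore cannot show how many calls unaffected clones or cultures would share. The opposite direction was called for 667 genes. Across 11704 genes at 1 CPM or more, the log2 fold changes of the clones had a Pearson r of 0.879 and a Spearman rho of 0.808. Both share the control libraries, which alone gave r of 0.501 ± 0.0116 (SD over 20 simulated data sets) and rho of 0.465, and a covariance of 0.0088 beside the observed 3.732. Genes are not independent replicates, and part of the agreement may come from the shared control. With a different control library for each clone, r was 0.861 to 0.879, rho 0.729 to 0.814 and the covariance 3.68 to 3.757. These control libraries are technical replicates of 1 population, so only their technical noise was unshared. Traits of that population stay in the fold changes of both clones, and this check cannot measure their part. On 7 of 20 chromosomes the median log2 fold change was also shifted by 0.3 or more in both clones, in the same direction. Such shifts of whole chromosomes, described in the closing section, can add to the shared calls and to r and rho. Their share was not measured. All p-values measure the spread between technical replicates of 1 population and 2 clones. With a threshold on size (glmTreat, log2 fold change above 1), 3580 genes passed in clone 1, 3388 in clone 2 and 2560 in both in the same direction.

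**Figure D2:**
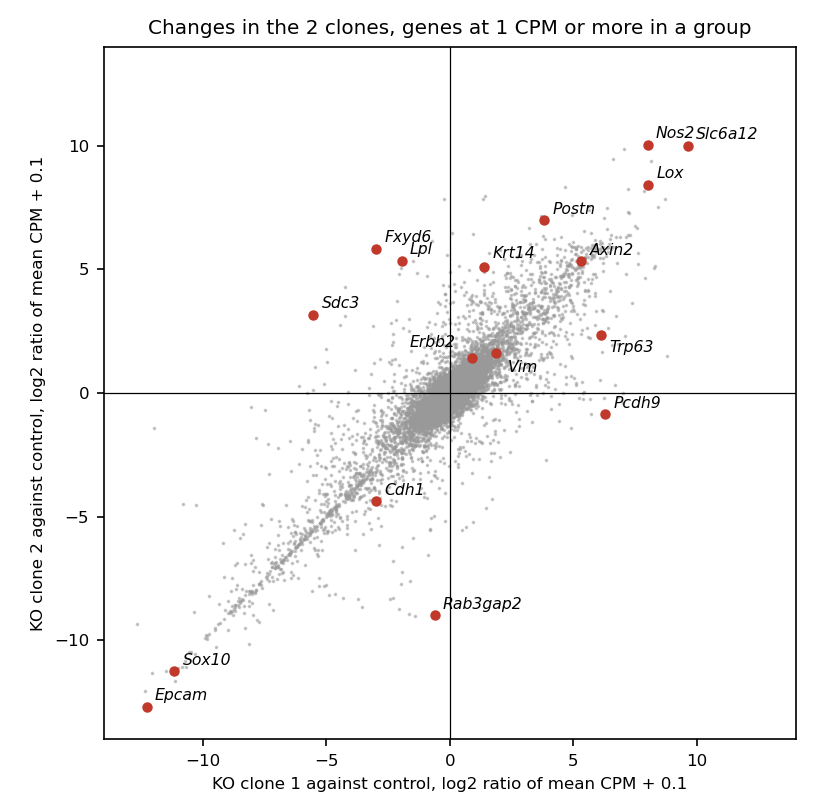
Each point is a gene, placed by the log2 ratio of its mean CPM (plus 0.1) in clone 1 to the control on the horizontal axis and in clone 2 to the control on the vertical axis. Named genes are marked; 8090 genes were called in the same direction in both clones and 667 in opposite directions.

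The next 12 genes had the largest fitted rise in both clones. Slc6a12, a betaine and GABA transporter, stood at 0.0238 ± 0.0302 CPM in the control, 97.3 ± 0.888 CPM in clone 1 and 127 ± 2.06 CPM in clone 2. Selenop, a selenium transport protein, stood at 0.985 ± 0.365 CPM in the control, 304 ± 14.3 CPM in clone 1 and 736 ± 42.6 CPM in clone 2. Nos2, the inducible nitric oxide synthase, stood at 0.220 ± 0.163 CPM in the control, 82.2 ± 2.56 CPM in clone 1 and 339 ± 13.3 CPM in clone 2. The cytokine gene Il6 had 0 counts in the control, so that clone 1 was at least 92.3-fold higher and clone 2 at least 609-fold higher. A fitted change against 0 counts is no bound, and the bound for clone 1 lies below the rise of Lox (263.6-fold). The serum amyloid genes Saa1 and Saa2, also at 0 in the control, reached 2.14 ± 0.238 CPM and 5.71 ± 0.126 CPM in clone 1 and 7.78 ± 1.19 CPM and 5.75 ± 0.793 CPM in clone 2; these paralogs can share reads. Wfdc21 had 1 count in the control and reached 5.02 ± 0.314 CPM in clone 1 and 17.5 ± 1.43 CPM in clone 2. Hopx, Sgcd, Rtn4rl2, Lgi2 and the glutamate transporter gene Slc1a3 completed the 12 genes, at 2.92 to 32.2 CPM in the clones and at most 0.103 CPM in the control.

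The 12 genes with the largest fitted fall had 0 counts in all 6 libraries of the clones. Their fitted order is no order of size, and their bounds do not show that they fell further than Epcam. Patj, a scaffold of tight junctions, stood at 143 ± 11.3 CPM in the control and was at least 10140-fold lower in clone 1 and at least 11340-fold lower in clone 2. Ripk4, a kinase of epithelial differentiation, stood at 96.3 ± 7.40 CPM in the control, and Ap1m2, an epithelial sorting adaptor, at 85.4 ± 9.81 CPM. The desmosomal cadherin genes Dsg2 and Dsc2 stood at 62.6 ± 2.19 CPM and 46.5 ± 6.06 CPM, and Tfap2c, a luminal transcription factor, at 45.4 ± 3.81 CPM. Tril, Galnt3, Evl, Map3k21, Btg3 and Ppic, between 40.7 and 90.2 CPM in the control, made up the rest. In all, 60 genes with 5 CPM or more in the control had 0 counts in both clones.

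Gene lists were compared by counts of members and by camera, which tests a list against all other genes; 5 of 30 lists passed in clone 1, 7 in clone 2 and 1 between the clones. With a correlation estimated from each list, 0 of the 90 camera tests passed (8 at an unadjusted p under 0.05), and 69 passed in fry, which tests a list by itself. The estimate rests on deviations between technical replicates. Neither it nor the preset 0.01 therefore measures how the members of a list vary together between clones or cultures. Adjusted over the list alone, the counts of members in each clone equalled those over all genes, except where a difference is given below. Log2 fold changes are given ± their standard error, first for clone 1 and then for clone 2.

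**Figure D3:**
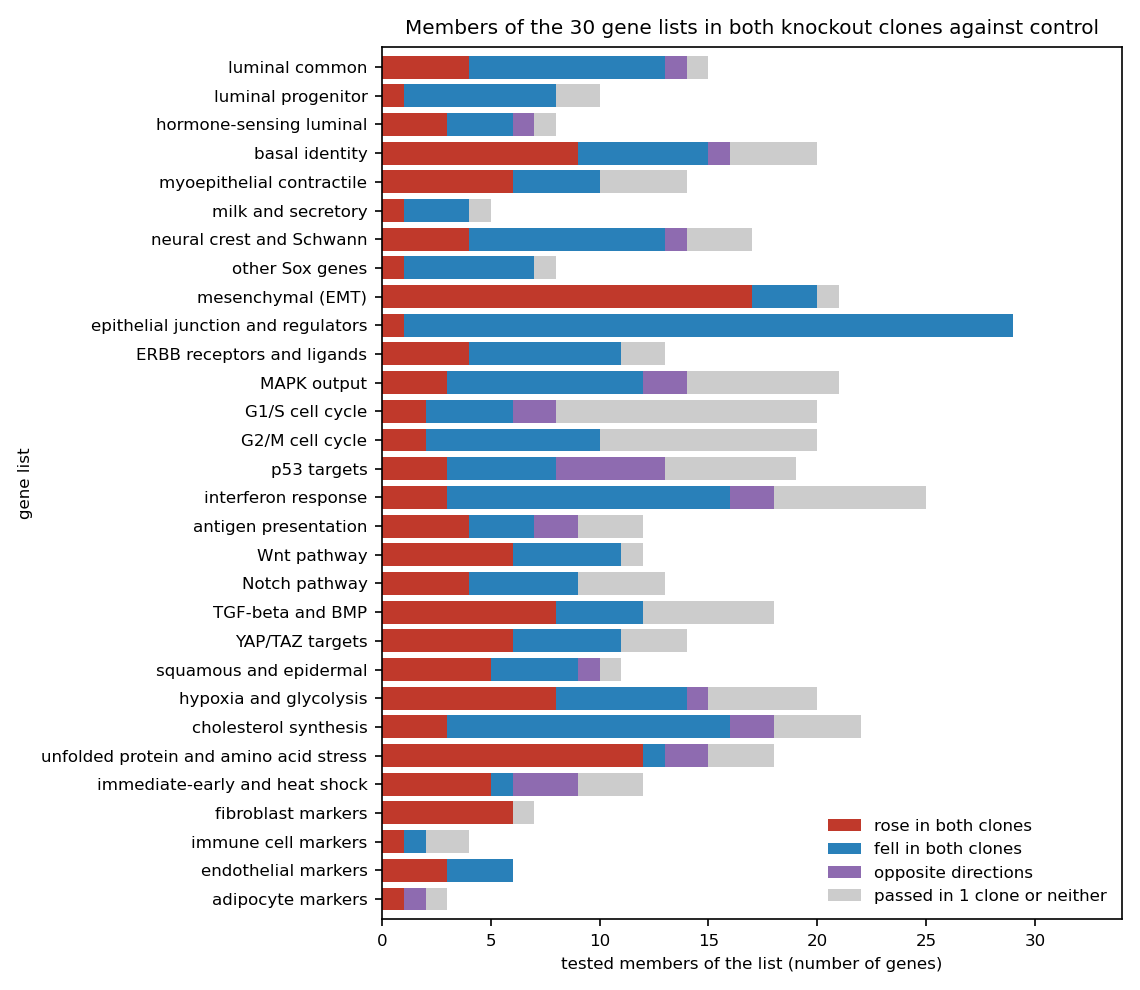
Bars give, for each of the 30 lists, the number of tested members that rose in both clones, fell in both clones, were called in opposite directions, or were called in 1 clone or none. In the list of epithelial junction genes 28 of 29 members fell, and in the mesenchymal list 17 of 21 rose.

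Of 29 genes of epithelial junctions and their regulators, 28 fell in both clones and 1 rose (adjusted p = 3.77e-09 in each clone, n = 3, camera; adjusted p = 0.48 in each with an estimated correlation). Epcam stood at 659.5 ± 10.9 CPM in the control, 0.0341 ± 0.0242 CPM in clone 1 and 0 counts in clone 2. Clone 1 held 7 Epcam counts, 20000-fold (95% counting interval 9700 to 49700) fewer than the control, and clone 2 held 0, at least 52170-fold fewer. The tight junction genes Cldn3, Cldn4 and Cldn7 stood at 520.4, 464.4 and 235.7 CPM in the control and at most at 0.0789 CPM in a clone. Esrp1, a splicing regulator of epithelial cells, went from 184 ± 2.23 CPM to 2 counts in clone 1 and 0 in clone 2. Cdh1, which encodes E-cadherin, fell to a smaller degree, at 341 ± 25.4 CPM in the control, 43.1 ± 1.83 CPM in clone 1 and 16.2 ± 1.49 CPM in clone 2. The exception was Ppl, a desmosomal linker, at 316.3, 763.1 and 897.6 CPM.

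Of 21 tested mesenchymal genes, 17 rose in both clones and 3 fell, and 18 rose in clone 2 adjusted over the list alone (adjusted p = 1.8e-04 in clone 1 and 5e-04 in clone 2; adjusted p = 0.48 in each with an estimated correlation). Lox stood at 12.1 ± 0.688 CPM in the control, 3199 ± 197 CPM in clone 1 and 4234 ± 380.1 CPM in clone 2. Vim, which encodes vimentin, stood at 906 ± 46.5 CPM in the control, 3283 ± 171 CPM in clone 1 and 2750.4 ± 65.4 CPM in clone 2. Postn, a matrix protein, had log2 fold changes of 3.83 ± 0.12 and 7.01 ± 0.14, and Col5a2, a fibrillar collagen, of 6.26 ± 0.42 and 3.53 ± 0.48. Snai2, a repressor of epithelial genes, rose from 0.398 ± 0.0694 CPM to 8.63 ± 0.697 CPM and 6.87 ± 1.31 CPM. Tnc, another matrix gene, fell, with log2 fold changes of -7.36 ± 0.23 and -2.95 ± 0.15. Markers of fibroblasts moved with this group: 6 of 7 tested rose in both clones, and 7 in clone 2 adjusted over the list alone (adjusted p = 0.00945 and 0.0279; adjusted p = 0.524 and 0.566 with an estimated correlation). Without control replicate 1 the fibroblast list missed the threshold in clone 2 (adjusted p = 0.0536). Both lists hold Col1a1, Col1a2, Col3a1 and Thy1, so that part of this joint movement is the same genes counted in each. The receptor gene Pdgfra stood at 7.83 ± 0.392 CPM in the control, 172 ± 2.02 CPM in clone 1 and 107 ± 4.13 CPM in clone 2, Fbln1 had log2 fold changes of 4.81 ± 0.13 and 4.98 ± 0.13 and Fbln2 of 1.30 ± 0.07 and 1.30 ± 0.07. Collagen I transcripts were scarce in every group, with Col1a2 at 0.680 ± 0.196 CPM in the control, 1.69 ± 0.107 CPM in clone 1 and 1.85 ± 0.304 CPM in clone 2.

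Of 15 general luminal genes, 9 fell in both clones, 4 rose and 1 was called in opposite directions (adjusted p = 0.19 in clone 1 and 0.0419 in clone 2; adjusted p = 0.614 for clone 2 with an estimated correlation). The difference between the clones had adjusted p = 0.934. The luminal keratin genes fell in both, Krt8 at 2393 ± 199.5 CPM in the control, 666 ± 39.5 CPM in clone 1 and 787 ± 54.0 CPM in clone 2 and Krt18 at 2305 ± 266 CPM in the control, 480.5 ± 35.4 CPM in clone 1 and 641 ± 37.3 CPM in clone 2. Ehf, an epithelial transcription factor, had log2 fold changes of 0.39 ± 0.12 and -2.44 ± 0.13, and its call in clone 1 was lost without control replicate 2 (0.33) or clone 1 replicate 1 (0.29). Gata3, a luminal transcription factor, stood at 88.9 ± 6.06 CPM in the control, 86.2 ± 2.32 CPM in clone 1 and 85.2 ± 1.09 CPM in clone 2 and passed in neither clone. Without control replicate 1 it passed in clone 2, at -0.13. Of 10 luminal progenitor genes, 7 fell in both and 1 rose (adjusted p = 0.0597 and 0.0191; adjusted p = 0.48 in each with an estimated correlation). Under a stricter expression filter clone 2 had adjusted p = 0.0776. Between the clones it was 0.768. Elf5, a transcription factor of luminal progenitors, fell from 43.3 ± 5.95 CPM to 0.285 ± 0.157 CPM and 0.214 ± 0.0367 CPM. Trf, the transferrin gene, was 1930-fold (95% counting interval 534 to 16000) and 1080-fold (95% counting interval 422 to 3970) lower, and Wfdc18 fell from 24.7 ± 2.49 CPM to 0 counts in clone 1, at least 1756-fold lower, and to 0.127 ± 0.0547 CPM in clone 2. Krt19 and Kit, with at most 13 and 10 counts in a library, were too low to test.

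Of 8 hormone-sensing luminal genes, 3 rose and 3 fell in both clones (adjusted p = 0.824 and 0.926), with 4 higher in clone 2 adjusted over the list alone. Wnt4 and Tbx3 rose, with log2 fold changes of 3.91 ± 0.08 and 3.06 ± 0.08 and of 4.86 ± 0.25 and 4.91 ± 0.25, and Prlr, the prolactin receptor gene, fell from 21.6 ± 2.41 CPM to 0.571 ± 0.0867 CPM and to 0 counts. Foxa1 stood at 0.460 ± 0.0841 CPM in the control and at 0 in both clones. Esr1, the oestrogen receptor gene, had log2 fold changes of 0.36 ± 0.14 and -0.45 ± 0.14. Its call in clone 1 was lost without control replicate 2 (0.26) or 3 (0.30) or clone 1 replicate 1 (0.32) or 2 (0.36) or with total counts (0.34), and that in clone 2 without clone 2 replicate 3 (-0.35). Of 5 milk and secretory genes, 3 fell and 1 rose in both clones (adjusted p = 0.587 and 0.74). Btn1a1, of the milk fat membrane, was 1230-fold (95% counting interval 340 to 10200) and 1380-fold (95% counting interval 381 to 11400) lower, and Xdh rose with log2 fold changes of 2.34 ± 0.09 and 2.31 ± 0.09.

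Basal genes went both ways. Of 20 tested, 9 rose in both clones, 6 fell and 1 was called in opposite directions (adjusted p = 0.48 in clone 1 and 0.74 in clone 2). Adjusted over the list alone, 13 rose and 7 fell in clone 1, and 10 rose and 7 fell in clone 2. Krt14, a basal keratin gene, stood at 3.80 ± 0.830 CPM in the control, 10.1 ± 0.770 CPM in clone 1 and 135 ± 6.10 CPM in clone 2. Trp63, which encodes the basal regulator p63, stood at 0.0751 ± 0.0153 CPM in the control, 12.2 ± 0.458 CPM in clone 1 and 0.786 ± 0.10 CPM in clone 2, and Jag2, a Notch ligand gene, had log2 fold changes of 3.50 ± 0.08 and 3.12 ± 0.08. Dll1, another Notch ligand gene, fell with log2 fold changes of -4.55 ± 0.10 and -3.20 ± 0.09. Krt5 and Krt17 had group means of at most 0.396 CPM. Krt5 had log2 fold changes of 1.92 ± 0.61 and 0.54 ± 0.67 and passed in clone 1, though not without control replicate 3 (1.63) or clone 1 replicate 3 (1.14). Krt17, with 6 counts in the control, was 4.05-fold (95% counting interval 1.6 to 12.2) and 5.83-fold (95% counting interval 2.44 to 16.9) higher. Its fitted log2 fold changes were 1.96 ± 0.81 and 2.48 ± 0.76. The call in clone 1 was lost in the fit blocked by replicate number (1.92, adjusted p = 0.06), in DESeq2 (2.03), without control replicate 1 (1.45) or 2 (1.97), without clone 1 replicate 1 (1.68) or 2 (1.90), and without clone 2 replicate 1 (1.96). In clone 2 it was lost without clone 2 replicate 2 (2.04).

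Of 14 contractile genes of myoepithelial cells, 6 rose and 4 fell in both clones (adjusted p = 0.768 and 0.577). Acta2, smooth muscle actin, went from 7 counts in the control to 0.562 ± 0.0110 CPM and 2.44 ± 0.383 CPM, 18-fold (95% counting interval 8.46 to 45.7) and 78.6-fold (95% counting interval 37.9 to 196) higher, while Tpm2 fell with log2 fold changes of -5.57 ± 0.23 and -6.12 ± 0.24 and Lmod1 with log2 fold changes of -7.37 ± 0.26 and -5.53 ± 0.21. Of 11 squamous and epidermal genes, 5 rose and 4 fell (adjusted p = 0.768 and 0.926). The stress keratin gene Krt16 rose from 0.231 ± 0.0249 CPM to 22.8 ± 2.40 CPM and 19.3 ± 0.788 CPM, and Sfn, a 14-3-3 protein gene of keratinocytes, fell with log2 fold changes of -7.20 ± 0.18 and -7.69 ± 0.19.

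Of 17 genes of neural crest and Schwann cells, the best known setting of Sox10, 9 fell and 4 rose in both clones (adjusted p = 0.734 and 0.335). Ngfr and L1cam, at 7.32 ± 0.250 CPM and 13.4 ± 0.969 CPM in the control, had 0 counts in both clones, and Pmp22, a myelin protein gene, rose with log2 fold changes of 4.70 ± 0.05 and 4.14 ± 0.05. Of 8 other Sox genes, 6 fell and 1 rose in both (adjusted p = 0.153 and 0.0597). Sox9, the exception, stood at 64.7 ± 4.16 CPM in the control, 154 ± 11.5 CPM in clone 1 and 129.8 ± 3.96 CPM in clone 2. Sox8 and Sox12, at 0.622 ± 0.0512 CPM and 2.80 ± 0.534 CPM in the control, had 0 counts in both clones, and Sox13 fell from 14.6 ± 1.24 CPM to 0.00955 ± 0.0165 CPM and 0.0462 ± 0.0182 CPM.

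Of 13 ERBB receptors and ligands, 7 fell and 4 rose in both clones (adjusted p = 0.758 and 0.566). Erbb2 stood at 554 ± 55.0 CPM in the control, 1034 ± 29.2 CPM in clone 1 and 1499.7 ± 75.6 CPM in clone 2; reads of the rat Neu transgene could align to it. Erbb3, its partner receptor, stood at 90.4 ± 9.16 CPM in the control, 35.1 ± 1.95 CPM in clone 1 and 36.4 ± 0.570 CPM in clone 2. The neuregulin genes Nrg1 and Nrg2 rose, with log2 fold changes of 2.04 ± 0.11 and 1.22 ± 0.11 and with 1.83 ± 0.10 and 2.17 ± 0.10, and the ligand genes Btc and Epgn fell, with log2 fold changes of -1.60 ± 0.23 and -1.83 ± 0.23 and with -2.48 ± 0.46 and -2.15 ± 0.43. Of 21 genes driven by MAPK signalling, 9 fell in both clones, 3 rose and 2 were called in opposite directions. In clone 1, 16 fell and 4 rose, and in clone 2, 9 and 6 (adjusted p = 0.0465 and 0.452; adjusted p = 0.524 for clone 1 with an estimated correlation). Between the clones the adjusted p was 0.277. The call in clone 1 was lost under DESeq2 size factors (adjusted p = 0.0502), total counts (0.053), the stricter filter (0.0734), without control replicate 1 (0.0536) or 3 (0.0567), and without the 1st replicate of every group (0.0625). Dusp5, a MAPK phosphatase gene, had log2 fold changes of -2.70 ± 0.07 and -1.73 ± 0.07, and Etv1 had a log2 fold change of -2.98 ± 0.18 in clone 1 and was 401-fold (95% counting interval 172 to 1240) lower in clone 2.

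Of 20 G1/S genes, 2 rose and 4 fell in both clones (adjusted p = 0.594 and 0.712), and of 20 G2/M genes, 2 rose and 8 fell (adjusted p = 0.233 and 0.0597; 0.014 for clone 2 in the fit blocked by replicate number). Uhrf1, a G1/S gene, had log2 fold changes of -0.52 ± 0.05 and -0.53 ± 0.05, and Cdc20, a mitotic activator, had log2 fold changes of -0.87 ± 0.06 and -1.07 ± 0.06. Of 19 p53 targets, 3 rose in both, 5 fell and 5 were called in opposite directions (adjusted p = 0.0597 and 0.621; 0.0445 for clone 1 in the blocked fit). Cdkn1a, a cell cycle inhibitor, stood at 189 ± 13.1 CPM in the control, 95.3 ± 1.55 CPM in clone 1 and 253 ± 2.89 CPM in clone 2, Pmaip1 had log2 fold changes of -3.48 ± 0.26 and 1.27 ± 0.19, and the death receptor gene Fas had log2 fold changes of 2.40 ± 0.07 and 2.21 ± 0.07.

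Of 25 interferon response genes, 13 fell in both clones, 3 rose and 2 were called in opposite directions, with 7 higher in clone 1 adjusted over the list alone (adjusted p = 0.48 and 0.0597). Usp18 fell from 11.4 ± 1.75 CPM to 0.344 ± 0.0951 CPM and 0.371 ± 0.124 CPM, and Ifi44 was 334-fold (95% counting interval 130 to 1230) and 249-fold (95% counting interval 114 to 680) lower. Of 12 antigen presentation genes, 4 rose and 3 fell in both (adjusted p = 0.94 and 0.587). Psmb8, an immunoproteasome subunit, had log2 fold changes of 5.41 ± 0.19 and 5.76 ± 0.19, and Nlrc5, an activator of MHC class I genes, had log2 fold changes of 3.87 ± 0.23 and 5.39 ± 0.23.

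Signalling lists were mixed. Of 12 Wnt pathway genes, 6 rose and 5 fell in both clones (adjusted p = 0.706 and 0.758). Axin2, a target of beta-catenin, stood at 2.86 ± 0.447 CPM in the control, 118 ± 1.87 CPM in clone 1 and 119.6 ± 1.34 CPM in clone 2, while the inhibitor gene Nkd2 fell from 115 ± 14.2 CPM to 0.315 ± 0.138 CPM and to 0 counts. Of 13 Notch genes, 4 rose and 5 fell (adjusted p = 0.94 and 0.712), and Notch4 rose with log2 fold changes of 1.49 ± 0.13 and 2.96 ± 0.13 while Notch3 fell with -4.37 ± 0.32 and -2.93 ± 0.28. Of 18 TGF-beta and BMP genes, 8 rose and 4 fell (adjusted p = 0.277 and 0.492). Tgfb2 had log2 fold changes of 2.27 ± 0.07 and 2.93 ± 0.07. Of 14 YAP/TAZ targets, 6 rose and 5 fell (adjusted p = 0.94 and 0.926); the receptor gene Axl had log2 fold changes of 3.20 ± 0.06 and 3.46 ± 0.06, Ankrd1 had log2 fold changes of -2.47 ± 0.07 and -2.82 ± 0.08 and Ccn2 had log2 fold changes of -4.08 ± 0.09 and -1.83 ± 0.09.

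Of 22 cholesterol synthesis genes, 13 fell in both clones, 3 rose and 2 were called in opposite directions (adjusted p = 0.053 and 0.00791; adjusted p = 0.48 for clone 2 with an estimated correlation; 0.0445 for clone 1 in the blocked fit). The difference between the clones had adjusted p = 0.407. Of 18 genes of unfolded protein and amino acid stress, 12 rose in both clones, 1 fell and 2 were called in opposite directions, with 4 lower in clone 1 adjusted over the list alone (adjusted p = 0.0176 and 0.00445; adjusted p = 0.524 and 0.48 with an estimated correlation). Phgdh, which starts serine synthesis, stood at 99.3 ± 9.40 CPM in the control, 588 ± 35.2 CPM in clone 1 and 615 ± 23.1 CPM in clone 2, Herpud1 had log2 fold changes of 2.91 ± 0.08 and 2.23 ± 0.08 and the chaperone gene Hsp90b1 had log2 fold changes of 1.44 ± 0.11 and 1.16 ± 0.11. Of 20 hypoxia and glycolysis genes, 8 rose and 6 fell (adjusted p = 0.94 and 0.492). Pfkp rose with log2 fold changes of 2.52 ± 0.06 and 1.98 ± 0.06, and Adm fell with log2 fold changes of -4.23 ± 0.13 and -3.66 ± 0.12. Of 12 immediate-early and heat shock genes, 5 rose in both clones, 1 fell and 3 were called in opposite directions, with 4 lower in clone 2 adjusted over the list alone (adjusted p = 0.233 and 0.786). Hspb1, a small heat shock protein gene, had log2 fold changes of 1.25 ± 0.10 and 2.64 ± 0.11, and Fosb had log2 fold changes of -4.71 ± 0.17 and -3.70 ± 0.16.

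Few markers of other cell types were high enough to test. Of 15 immune markers 4 were tested, with 1 higher and 1 lower in both clones (adjusted p = 0.94 and 0.422) and 3 higher in clone 2, and Lyz2, the lysozyme gene, reached 6.36 ± 0.954 CPM in clone 2. Csf1r, the marker that fell, had log2 fold changes of -1.01 ± 0.42 and -1.42 ± 0.43. Its call in clone 1 was lost in the blocked fit (-0.97, adjusted p = 0.0818), in DESeq2 (-1.03), with only the libraries of the groups compared (-1.01), without control replicate 2 (-0.57), without clone 1 replicate 2 (-0.73) or 3 (-1.04), and without any of the clone 2 replicates (-1.009 to -1.005). That in clone 2 was lost without control replicate 2 (-0.98). Adjusted over the list alone, 1 immune marker rose and 0 fell in clone 1. Of 6 tested endothelial markers, 3 rose and 3 fell (adjusted p = 0.926 and 0.804); Kdr, a VEGF receptor gene, stood at 16.2 ± 0.947 CPM in clone 1 and Eng fell with log2 fold changes of -3.31 ± 0.09 and -2.98 ± 0.09. Of 3 tested adipocyte markers, 1 rose in both and 1 was called in opposite directions (adjusted p = 0.758 and 0.113), with 2 higher in clone 1 adjusted over the list alone and 3 of 3 higher in clone 2 (median log2 fold change 4.94); Fabp4 had log2 fold changes of 2.68 ± 0.17 and 3.83 ± 0.17. Plin4 had 1.4992 ± 0.646 and 4.94 ± 0.52, and in clone 1 it missed the threshold, but passed in the blocked fit (1.4999, adjusted p = 0.0104) and without control replicate 1 (2.09) or clone 1 replicate 3 (1.81). Median, mean and direction of the test differed in sign for the hormone-sensing, Wnt, YAP/TAZ, hypoxia and endothelial lists in both clones, for the antigen presentation, Notch and immediate-early lists in clone 1, and for the TGF-beta and squamous lists in clone 2.

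The comparison of the mean of the clones with the control called 10780 genes, 5279 higher and 5501 lower, of which 2070 and 2167 changed at least 2-fold; 3432 passed with a threshold on size. With the counts summed per population, so that each clone was 1 sample, 568 genes passed, 245 higher and 323 lower, with 1 residual degree of freedom.

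The last comparison asked how the clones differed from each other. Clone 2 held far more transcript of the basal keratin gene Krt14 and of the matrix gene Postn than clone 1 (135 against 10.1 CPM and 895 against 99.2 CPM), and less of the basal regulator Trp63. Of 13928 genes, 8018 (57.6%) differed, 4191 higher and 3827 lower in clone 2, of which 1056 and 947 differed at least 2-fold and 1186 passed with a threshold on size. Several genes present in clone 2 had 0 counts in clone 1. Fxyd6, a sodium pump regulator, stood at 45.2 ± 2.19 CPM in clone 2, at least 3190-fold higher, and Sdc3, a syndecan gene, at 41.3 ± 1.91 CPM, at least 2916-fold higher. Tdrp, Pla2r1, Cers6, Irak3, Gata4 and Slc35g1 stood at 10.9 to 16.0 CPM in clone 2 and at 0 in clone 1. Conversely, Pcdh9, Sdk1, Epdr1, Gcnt4, Pxdc1 and Cyp2f2 had 0 counts in clone 2 and 1.45 to 14.1 CPM in clone 1. Rab3gap2 was 4260-fold (95% counting interval 1180 to 35200) lower in clone 2, and Rgs19 1710-fold (95% counting interval 584 to 8290) lower. Lpl, which encodes lipoprotein lipase, stood at 0.594 ± 0.251 CPM in the control, 0.0799 ± 0.0819 CPM in clone 1 and 28.3 ± 2.87 CPM in clone 2. Of the 30 lists, p53 targets passed between the clones, with 12 of 19 higher and 3 lower in clone 2 and 4 lower adjusted over the list alone (adjusted p = 0.0438; adjusted p = 0.48 with an estimated correlation). This call was lost with total counts (0.0543) and without control replicate 1 (0.0536) or 3 (0.0569), clone 1 replicate 2 (0.0531) or 3 (0.0533) or clone 2 replicate 3 (0.0519). The adjusted p was 0.72 for epithelial junction genes, 0.244 for mesenchymal genes and 0.561 for basal genes.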

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

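The test of the difference between the clones was chosen before the values were known. It asked whether a named gene differed between clone 2 and clone 1 by more than a log2 difference of 1 (glmTreat, adjusted p under 0.05), and whether a list differed in camera. Of 184 named genes, 57 passed, 32 higher and 25 lower in clone 2, with a highest adjusted p of 0.0394, and 1 of 30 lists passed. Over all genes 1186 of 13928 passed (8.52%). The share of named genes (31.0%) is not comparable, since 16 of the 57 were named for their difference between the clones and 9 more were called in opposite directions against the control; of 18 mammary genes named in advance and tested, 5 passed. Log2 differences below are clone 2 minus clone 1, each over 3 technical replicates per clone, so that they describe 2 clones and not a genotype.

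Clone 2 was higher in Lpl (8.43), Pmaip1 (4.75), Lyz2 (4.50), Tnc (4.40), Krt14 (3.75), Des (3.58), Plin4 (3.44), Postn (3.17), Ciita (2.81), Il6 (2.70), Atf3 (2.52), Ccn2 (2.25), Acta2 (2.12), Nos2 (2.04), Saa1 (1.86), Wfdc21 (1.80), Nlrc5 (1.51), Notch4 (1.46), Cdkn1a (1.41), Hspb1 (1.39), Dll1 (1.35) and Selenop (1.28). It was lower in Kdr (-5.07), Dsg3 (-4.31), Trp63 (-3.95), Krt15 (-2.92), Ehf (-2.82), Col5a2 (-2.73), Slc1a3 (-2.37), Rtn4rl2 (-1.97), Epha4 (-1.83), Ltbp2 (-1.74), Cdh1 (-1.41) and Tfap2a (-1.28), and in Etv1 (-5.56), which was 50.6-fold (95% counting interval 21.4 to 157) lower on 5 counts. The p53 targets were the list that differed (adjusted p = 0.0438, with 12 of 19 members higher and 3 lower; 1.57e-06 to 0.48 over its alternatives).

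Other genes had 0 counts in 1 clone, so that their log2 difference is a bound against 3 counts over the group. Clone 2 was higher by at least 11.64 for Fxyd6, 11.51 for Sdc3, 10.14 for Tdrp, 9.85 for Pla2r1, 9.68 for Cers6, 9.62 for Irak3, 9.61 for Gata4, 9.60 for Slc35g1 and 3.16 for Wfdc18. The bound was -10.12 or lower for Pcdh9, -10.00 for Sdk1, -9.53 for Epdr1, -8.96 for Gcnt4, -8.05 for Pxdc1, -6.83 for Cyp2f2, -5.50 for Prlr, -4.62 for Nkd2 and -1.38 for Epcam. With 2 or 3 counts in clone 2, the ratios were -12.06 for Rab3gap2, -10.74 for Rgs19 and -5.14 for Oas2. As folds, Rab3gap2 was 4260-fold (95% counting interval 1180 to 35200) lower, Rgs19 1710-fold (95% counting interval 584 to 8290) lower and Oas2 35.2-fold (95% counting interval 9.36 to 297) lower.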

How the results depend on the processing

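The settings without the 1st replicate of every group were added after the data were seen. So was the agreement of the clones with a different control library for each. All other alternatives were fixed in advance. A threshold on size (glmTreat) gave 3580 genes in clone 1, 3388 in clone 2, 2560 in both in the same direction, 3432 for the mean of the clones and 1186 between the clones, which follows from its stricter question. Counts summed per population gave 568 genes for the mean of the clones, 245 higher and 323 lower, and 3192 at an unadjusted p under 0.05; this setting had 1 residual degree of freedom. Under all other alternatives the counts of genes stayed within 1.5 times the reported ones. With replicate number as a block they were 11420 in clone 1, 11257 in clone 2, 8807 in both, 11524 for the mean and 9439 between clones, and without the 1st replicate of every group 11202, 10971, 8585, 11292 and 8892. Leaving out 1 library at a time gave 10129 to 10843 genes in clone 1, 9886 to 10544 in clone 2, 7593 to 8246 in both, 10212 to 10837 for the mean and 7030 to 8556 between the clones. Of the 13 list calls, 0 held with an estimated correlation, 69 of 90 tests passed in fry, 16 with the replicate block, 14 without the 1st replicates, and 10 to 19 with 1 library left out. In fry, which tests a list by itself, the direction reversed for basal genes in clone 2 (adjusted p = 0.00195; 0.00195 to 0.893 over all alternatives), neural crest genes in clone 1 (0.00226; 0.00226 to 0.893) and YAP/TAZ targets in clone 1 (0.000499; 0.000499 to 0.992); the cause was not tested. Calls of lists gained by leaving out 1 library were G2/M genes in clone 2 without control replicate 2 (0.0498) or clone 2 replicate 1 (0.0404), and without control replicate 2 interferon genes (0.0451) and other Sox genes (0.0498) in clone 2, luminal progenitor genes in clone 1 (0.0461) and adipocyte markers between the clones (0.0498; 0.0433 without clone 2 replicate 2). Cholesterol genes in clone 1 passed without control replicate 2 (0.0451), clone 1 replicate 1 (0.0494) or 3 (0.0457), or clone 2 replicate 1 (0.0488) or 2 (0.0447). The log2 fold change of Sox10 for the mean of the clones was -13.56, and the same with the block; it ranged from -13.77 to -13.27 with 1 library left out, apart from clone 1 replicate 2, without which clone 1 is at 0 counts and the fitted -15.64 is no bound. No named gene reversed. With 1 library left out, 54 of their tests lost the call, 3 gained it and 3255 kept their side of the threshold. Fits of only the groups compared do not exist for the mean of the clones, which needs all groups. With at least 65805296 counts per library, depth limits only genes near the floor of 0.0127 to 0.0142 CPM per group.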

Other observations

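The gene families here, and all tests below except the correction for GC content and length and the counts of splits, were chosen after the results were seen, so that the counts of family members below describe and do not test. The homeobox genes of the Hoxa cluster fell together. All 7 tested members fell in both clones. Hoxa7 stood at 15.8 CPM in the control and at 0 counts in both clones. Of 20 clustered protocadherins, neuronal adhesion molecules, 13 rose in both clones and 0 fell in both, with Pcdhgc3 at 66.7, 333.3 and 293.5 CPM in the control, clone 1 and clone 2. Most of the others stood under 1 CPM in every group, such as Pcdhga5 at 0.017, 0.445 and 0.110 CPM. Pcdhb17 was called lower in clone 2, with a log2 fold change of -1.59. Of 11 claudins, 9 fell in both and 0 rose.

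Acute-phase and nitric oxide genes were picked because they rose, so that their count is not a test; 15 of 15 rose in both clones. Saa3, a serum amyloid gene, stood at 1.37 CPM in the control, 142.3 CPM in clone 1 and 1031.7 CPM in clone 2. Hp, which encodes haptoglobin, stood at 0.54, 96.1 and 193.5 CPM, and Acod1, which makes itaconate in activated macrophages, at 1.73, 428.1 and 532.9 CPM. Tlr2, a receptor of bacterial lipoproteins, stood at 22.3, 143.6 and 210.5 CPM. Ribosomal protein genes fell by smaller amounts, 22 of 31 of the small subunit in both clones (median log2 fold changes -0.475 and -0.678). Of 45 of the large subunit, 26 fell in both clones (medians -0.297 and -0.355).

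Median expression was shifted on some chromosomes. Over 11697 genes at 1 CPM or more, the median log2 fold change was 0.3 or more from that of the other chromosomes in both clones for 7 of 20 chromosomes: higher on 3 (0.56 in clone 1 and 0.448 in clone 2), 10 (0.447 and 0.405) and 14 (0.632 and 0.513), and lower on 4 (-0.545 and -0.579), 7 (-0.463 and -0.464), 12 (-0.419 and -0.534) and 19 (-0.48 and -0.493). The SD of the chromosome medians was 0.338, above the highest of 1000 shuffles of the genes (0.0594), which argues against scatter by chance, and all 7 chromosomes kept their shift after a correction for GC content and length. A candidate explanation is a difference in DNA copy number: when chromosomes were chosen by the genes of every other window of 50 neighbouring genes, the same 7 were found, and 37 of their 38 remaining windows (97.4%) lay on the same side in both clones, against at most 63.2% in 1000 random assignments of windows to chromosomes. This shows that the shift extends along the chromosomes and does not show its cause. The shift may lie in the control population or in both clones, and DNA was not analysed here. Between the clones 4 chromosomes differed by 0.3 or more, in clone 2 relative to clone 1: 13 (-0.656), 1 (0.343), 6 (0.335) and 9 (0.343). Chromosome 8 differed in parts, with its first 2 windows at 0.549 and 0.493 and windows 4 to 13 at -0.343 to -0.589.

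The loss of epithelial and gain of mesenchymal transcripts was set against fibroblasts in place of the tumour cells. Col1a1, Col1a2, Col3a1, Dcn and Lum, which fibroblasts make in large amounts, reached at most 2.95 CPM in a clone. These values argue only against fibroblasts rich in these transcripts, which were picked after the results were seen. Of the fibroblast list, 6 of 7 tested members rose in both clones. Among them, Pdgfra stood at 102.58 CPM or more in every library of the clones and at most at 8.11 CPM in the control. The design leaves open whether the change came with Sox10 loss or with the choice of single cells, since each clone descends from 1 cell and the control is a bulk population; this biological difference was not tested, and no edited clone that kept Sox10 was analysed here.

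Transcripts silent in both clones were compared with independent losses. Of 9939 genes at 5 CPM or more in the control, 127 had at most 3 counts in clone 1 and 127 in clone 2, and 89 were the same genes, against 1.62 for independent losses. The value of 1.62 takes every gene as equally likely to be lost. The ratio of 54.8 therefore argues only against independent losses that strike all genes alike. A shared proneness of some genes to loss, or the choice of single cells, may account for it. So may descent of both clones from a common subset of the parent cells, or a common response to Sox10 loss. None of these was tested. Of the 9939 genes, 4 silent in clone 1 (Cdcp1, Bckdhb, Hebp1 and Slc35g1) stood at 5 CPM or more in clone 2, and 3 silent in clone 2 (Gcnt4, Rgs19 and Rab3gap2) in clone 1.

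The genes beside Sox10 were tested for a deletion reaching them. Polr2f on the 3' side had a lowest log2 fold change of 0.336 in a clone, which argues against its loss. Gm10863 on the 5' side had -1.578 in clone 1, between the bounds set for the test, so that a deletion on that side stays open.

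Other splits of the libraries were counted for each contrast. They regroup technical replicates of 3 populations, so they set differences between populations against technical noise and cannot say whether chance differences between cultures or clones account for the calls; the bound set in advance for these counts overlooked this. For the mean of the clones, 1 of 84 splits, the real one, gave 10780 genes; with the clone 1 libraries as control there were 9438, the highest other, and with the clone 2 libraries 9057, so that each population set against the others called many genes. For genes changed in both clones in the same direction, 1 of 100 groupings, the real one, gave 8090 genes, and the highest other 6666. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real values and the highest of the other splits were 10653 and 0 genes for clone 1, 10367 and 0 for clone 2, and 8018 and 0 between the clones. For lists they were 5 and 6 in clone 1, where 3 of 10 splits gave as many, 7 and 6 in clone 2, and 1 and 3 between the clones, where 4 of 10 gave as many. Replicate number paired the libraries clearly only for replicate 1. For genes, the splits that part as many same-numbered pairs as the real one also had 0 as their highest.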
